A study of Mus musculus with 12 samples.

How the data were processed

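Gene expression was measured in 12 cultures of mouse bone marrow cells, with 1 array per culture and 3 cultures in each of 4 groups. The starting cells were hematopoietic stem and progenitor cells of C57Bl/6 mice, sorted as lineage-negative, Sca-1-positive and Kit-positive. They were grown for 7 days in serum, stem cell factor and granulocyte/macrophage colony-stimulating factor. The groups received growth factors only, 5 mM lithium chloride, 1 mM valproic acid, or both agents. The series' design text calls the triplicates independent biological samples. Labelled cRNA was made from 100 ng of total RNA, per the labels' protocols.

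The authors deposited a table of bead intensities, 1 value per probe and array on a linear scale and not normalized between arrays, with a detection p-value beside each intensity. The submitters' processing notes name GenomeStudio, and whether a background had been subtracted from these intensities is not given in the sources used here. The deposited detection p-values moved in steps of 1 in 798, as ranks among negative control probes would. The authors also deposited a table of log2 values for the same 12 samples, in which every array had the same distribution, which quantile normalization gives. That table served as an alternative. A further deposited file, a probe profile made with GenomeStudio 1.1.1 for the MouseRef-8 version 2 array per the file headers, held 192 columns of per-sample values for 24 arrays. Its columns were named by chip and position, which match no sample label, and its probes were keyed by a number that the other tables lack, so these columns were not used here.

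Table columns were assigned to samples by name alone. By rank correlation of at least 0.999996, each array of the intensity table had a counterpart in the table of log2 values within the same group, but for 5 of the 12 arrays the counterpart carried another replicate number. Replicate numbers in the text are those of the intensity table. Comparisons between groups do not depend on these numbers.

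Intensities were background corrected by the normexp method with the background inferred from detection p-values, an offset of 16 was added, and the arrays were quantile normalized on the log2 scale (limma 3.58.1, function neqc, in R 4.3.3). Of 25697 probes, the 12907 with a detection p-value under 0.05 on at least 3 of the 12 arrays were tested. A linear model with 1 mean per group was fitted to all 12 arrays with 8 residual degrees of freedom. Moderated statistics came from limma's eBayes without a trend, two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A probe counted as changed at an adjusted p under 0.05. The 6 pairwise comparisons, the interaction of the agents (the lithium effect with valproic acid minus that without it) and an overall test of the 4 groups were fixed before the data were examined. No array pair held identical values.

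The files used do not pair probe identifiers with genes. The plan of 1 probe per gene could therefore not be applied, every probe was tested on its own, and a count of probes is not a count of genes. The 32 gene lists fixed before the data were examined and the rule for named genes were not run. That rule, the largest changes past the threshold with all treated arrays on one side of all control arrays, was kept for probes but limited, after seeing the data, to the comparison of the combination with growth factors only and to 2 probes that rose and 2 that fell.

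Where a probe had a detection p-value of 0.05 or more on every array of a group, a fold against that group is given as a lower bound on the background-corrected scale. It sets the brighter group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own value. Shared control arrays were allowed for by 100 simulations of unchanged groups with each probe's fitted SD. The SD of changes across probes and the slopes between effects were corrected for the mean squared standard error. Standard errors of these slopes and of covariances came from leaving out each array in turn (jackknife). For slopes and SDs of changes it was pooled over all 12 arrays, which gives a larger value than the sum within groups used for covariances. The covariance of both agents' changes was also taken with different control arrays for each agent. The fit was tested on simulated data for the comparison of the combination with growth factors only, over 12907 probes with 50 probes changed at each size. It recovered 0 of 50 at a log2 change of 0.5, 12 of 50 at 1, 41 of 50 at 2 and 48 of 50 at 3, with 3 false calls. In the same simulation 6 unchanged probes had a called interaction. Far fewer probes were changed in it than were called in the real comparison, which makes the adjusted threshold stricter. It also leaves out the sets of arrays described below. Its recovered shares and false calls therefore do not describe the fit to the real data.

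The 9800 probes detected on no array served to look for technical structure. Arrays whose rank correlation with another array over these probes exceeded 0.25 formed one set of 8, and the other 4 arrays were treated as a second set. No label names these sets. They were defined after seeing the data, from background signal and not from a treatment response, and results with the set as a block and within each set stand beside the 12-array results. Alternatives fixed beforehand were median scaling, no background correction, the deposited log2 values, no filter or a filter on all 12 arrays, eBayes with trend and robust, only the arrays of the groups compared, the replicate number as a block, an added fold threshold of 2, and leaving out each array. The chip as a block was not run, as no table used names the chip of a sample. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision.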

Results

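Valproic acid, an inhibitor of histone deacetylases, and lithium, an inhibitor of glycogen synthase kinase 3, were each added to differentiating mouse hematopoietic stem and progenitor cells, alone and together. The 4 groups of 3 arrays form a full crossing of both agents, so that each agent's effect can be read with and without the other. Between 42.3% and 46.8% of probes were detected per array, and the median raw intensity ran from 96.3 to 142. The first 3 principal components of the normalized values carried 57.7%, 21.9% and 7.69% of the variance.

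The arrays fell into 2 sets that the groups do not explain. Over probes detected on no array, 8 arrays correlated with each other at 0.469 to 0.550, while every other pair of arrays lay between 0.121 and 0.207. The set of 4 held growth factors only replicate 1, valproic acid replicate 1, and replicates 2 and 3 of the combination, and no lithium array. In the deposited log2 table these arrays carried number 1, apart from replicate 3 of the combination, which carried number 2. Number 1 there was also on lithium replicate 3, from the set of 8. Over tested probes, deviations from the group means correlated at 0.557 to 0.773 between arrays of the set of 4 from different groups. Number 2 of the log2 table joins combination replicate 3 to replicates 2 of the other groups, all in the set of 8. Its deviations correlated with theirs at -0.444 (growth factors only), -0.483 (valproic acid) and 0.0205 (lithium). Pairing by number can therefore not be told apart from the sets there. Number 3, wholly within the set of 8, had a lowest value of 0.0442. The sets enter its deviations too, as every group mean but lithium's includes arrays of the set of 4. With set as a term in limma, 7597 probes (58.9%) differed between the sets, 4114 of them higher in the set of 4.

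**Figure D1:**
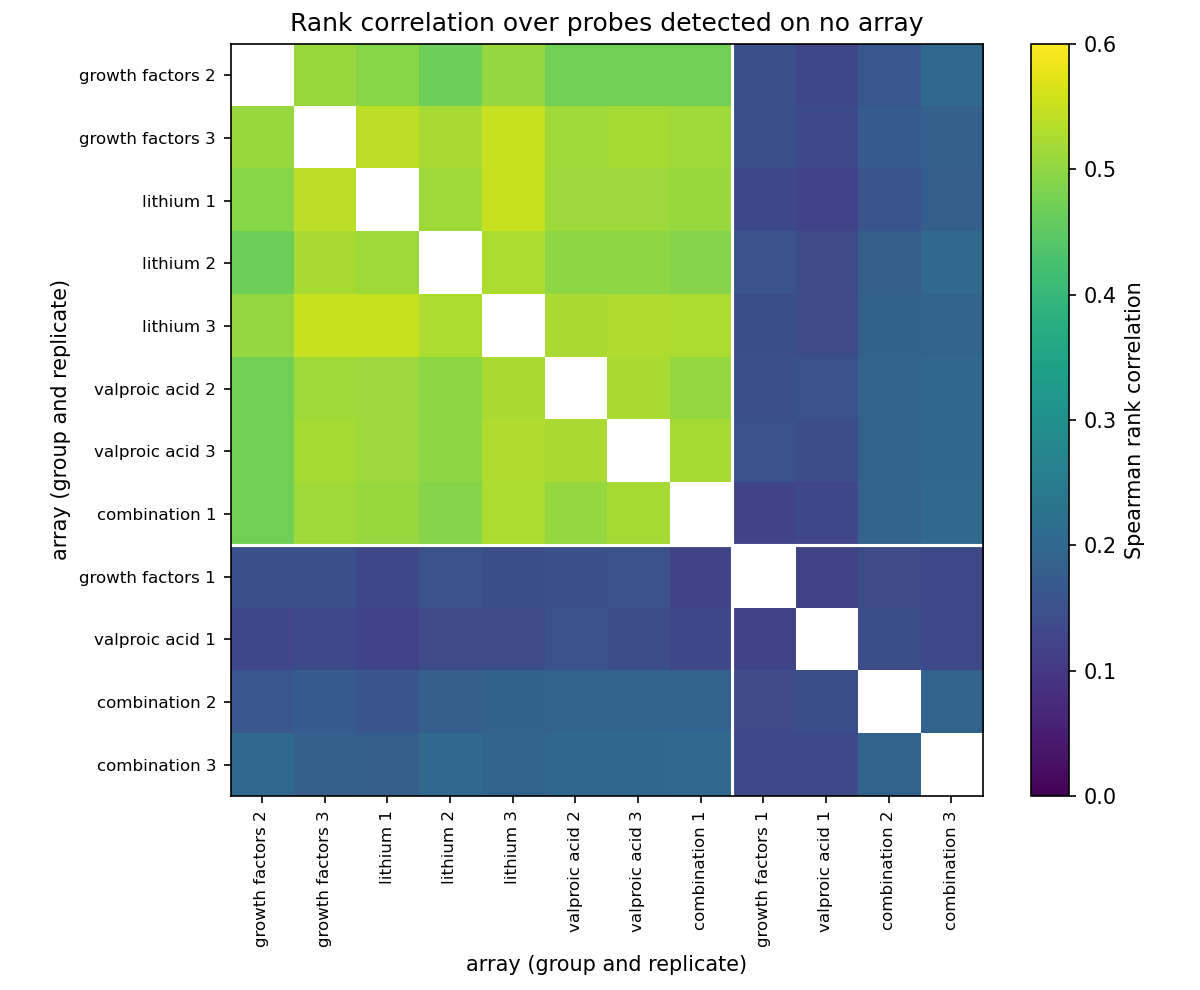
Spearman rank correlation between arrays over the 9800 probes detected on no array, with both axes listing arrays by group and replicate and white lines parting the sets. The 8 arrays at the upper left correlated at 0.469 to 0.550, and all other pairs at 0.121 to 0.207.

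Valproic acid alone changed 25.2% of the probes tested. Against growth factors only, 1707 probes rose and 1541 fell, together 3248. Fitted changes of at least 8-fold were more often falls, with 88 probes down and 28 up. Probes undetected in a group are among them, and the size of their changes depends on the background level. The SD of the changes across probes, net of error, was 0.77 on the log2 scale, and 0.53 without background correction. A block for the set gave 5939 probes (3311 up, 2628 down). Within the set of 8 arrays 5051 passed, and within the set of 4 1459, where 1 array stood against 1 and both were assumed to vary like the pair of combination arrays, with 1 residual degree of freedom. Of the 5051 probes called in the set of 8, 4748 (94.0%) moved the same way in the set of 4, against 77.0% of all tested probes. Under median scaling in place of quantile normalization the balance turned, to 1164 up and 1691 down.

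Lithium alone changed 8.58% of the probes tested. Against growth factors only, 454 probes rose and 654 fell, together 1108, with an SD of changes net of error of 0.47 on the log2 scale. Without background correction that SD was 0.33. The balance depended on the sets and the scaling. A block for the set gave 3164 probes, 1638 up and 1526 down, and the set of 8 arrays alone gave 3069. Median scaling gave 292 up and 721 down, with the median log2 change of all probes at -0.12. No lithium array lay in the set of 4. The count was 567 without growth factors only replicate 3, and 725, 458 and 448 without lithium replicates 1, 2 and 3.

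The combination changed 39.5% of the probes tested. Against growth factors only, 2881 probes rose and 2218 fell, together 5099. By fitted change 234 probes fell at least 8-fold against 56 that rose as much. Probes undetected in a group are among them, and the size of their changes depends on the background level. The SD of changes net of error was 1.07 on the log2 scale, and 0.74 without background correction. A block for the set gave 7160 probes, the set of 8 arrays, with 1 array of the combination, 5448 and the set of 4 arrays, with 1 of growth factors only, 4241. A lone array was assumed to vary like the other groups of its set. Of those called in the set of 8, 5285 (97.0%) moved the same way in the set of 4, against 81.9% of all tested probes, and changes correlated at 0.914 across probes, which are not independent replicates. Under median scaling the balance turned to 2238 up and 2584 down.

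**Figure D2:**
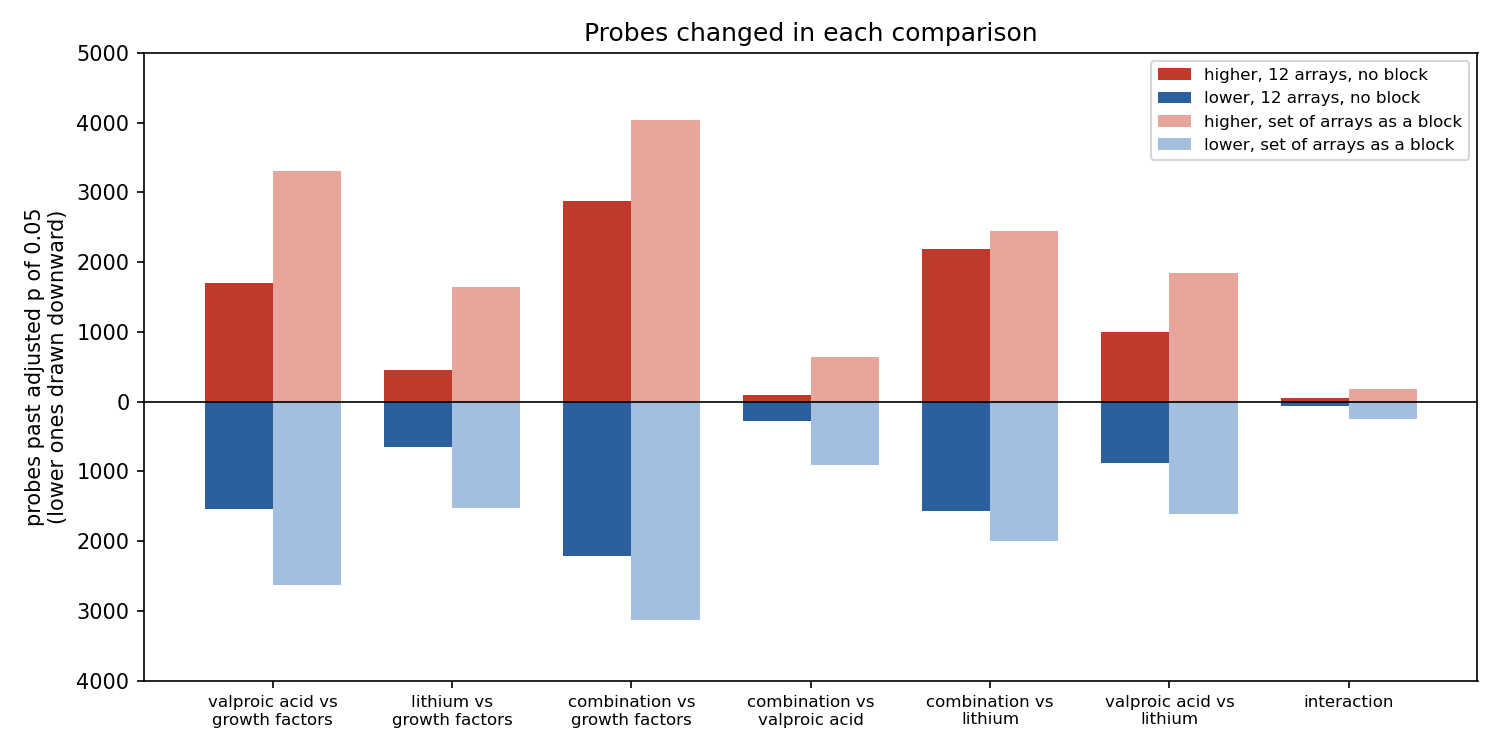
Numbers of probes past an adjusted p of 0.05 in each comparison, higher ones drawn upward and lower ones downward, from the 12-array fit (dark) and with the set of arrays as a block (light). The combination against growth factors only had 2881 probes higher and 2218 lower without the block.

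Probe ILMN_2719256 rose under each treatment. Its normalized log2 intensity was 6.35 ± 0.22 (SD, n = 3) with growth factors only, 10.59 ± 0.36 with lithium, 11.07 ± 0.39 with valproic acid and 13.01 ± 0.17 with both. On background-corrected values, to which all folds here refer, the combination was 102-fold above growth factors only (log2 change 6.67, SE 0.25, limma adjusted p = 2.23e-09). Probe ILMN_1212702 was detected on 0 of 3 arrays with growth factors only and on all arrays of the treated groups, so the combination was at least 47.4-fold higher on the corrected values (adjusted p = 1.48e-07 in limma). Probe ILMN_2736774 stood at 13.46 ± 0.47 with growth factors only and 8.76 ± 0.46 with valproic acid (log2 change -4.71, SE 0.31, limma adjusted p = 7.04e-07). Its change with lithium alone was -1.04 and did not pass (limma adjusted p = 0.059), but with the set as a block it was -1.27 and passed (limma adjusted p = 0.000633). Settings fixed beforehand also differed on this change. It passed under median scaling (-1.31, limma adjusted p = 0.0164), without background correction, on the deposited log2 values and with trend and robust eBayes. It did not pass without the filter or with the intensity table's replicate number as a block. With both agents ILMN_2736774 was detected on 0 of 3 arrays, at least 292-fold lower on the corrected values than with growth factors only (limma adjusted p = 2.23e-09). Probe ILMN_1250421 went from 12.46 ± 0.66 to 8.02 ± 1.17 with valproic acid and was not detected with both agents, at least 146-fold lower on the corrected values (limma adjusted p = 3.78e-07). Lithium alone left it at 12.14 ± 0.76, which did not pass (limma adjusted p = 0.777). The sizes depended on the correction: without it the log2 changes under the combination were 5.43 for ILMN_2719256, 4.15 for ILMN_1212702, -6.37 for ILMN_2736774 and -5.42 for ILMN_1250421, so the bounds do not hold on uncorrected values. On the deposited log2 values they were 5.59, 4.45, -6.57 and -5.64 in the same order, and all passed under both settings. All 3 arrays of the combination lay on the same side of all 3 arrays with growth factors only for each of them, as the rule that chose them required. The files do not pair these probes with genes.

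**Figure D3:**
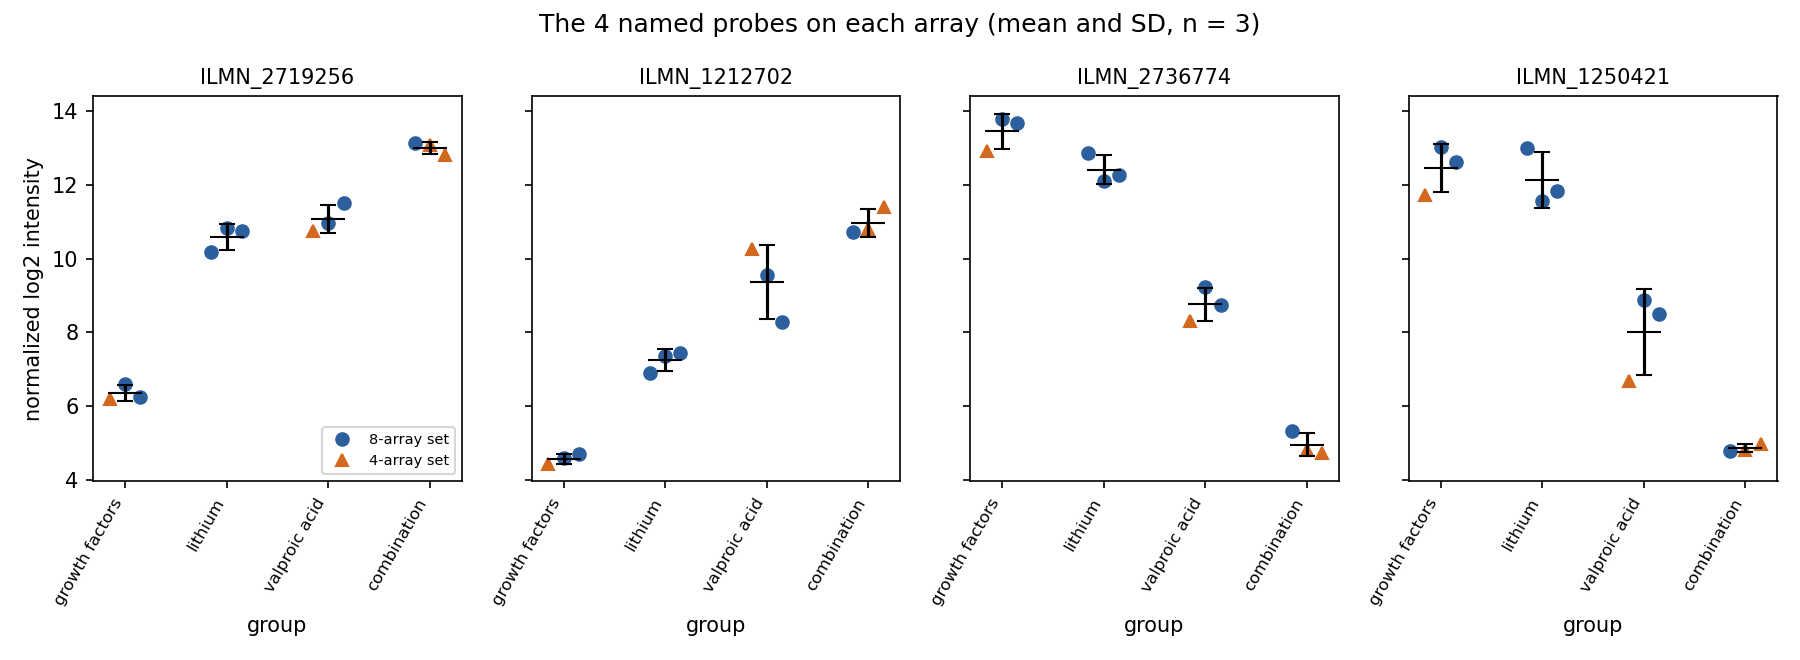
Normalized log2 intensity of the 4 named probes on each array by group, with circles for the set of 8 arrays, triangles for the set of 4, and bars for the mean and SD of 3 arrays. ILMN_2719256 rose from 6.35 to 13.01 and ILMN_2736774 fell from 13.46 to 4.95 between growth factors only and the combination.

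Some probes were detected on all arrays of one group and none of another. Under the combination 339 probes were detected on all 3 arrays and on no array with growth factors only, and 240 showed the opposite. For valproic acid alone these numbers were 218 and 142, and for lithium alone 87 and 103. Of these, 300 of 339 gained and 235 of 240 lost under the combination also passed the limma test, as did 178 of 218 and 134 of 142 for valproic acid, but 38 of 87 and 64 of 103 for lithium. Other splits of the same 6 arrays gave in 1 direction at most 239, 113 and 62 probes, so the 240 lost under the combination hardly exceeded them. At a detection p-value under 0.01, a limit chosen after seeing the data, valproic acid gave 179 and 152 probes and another split 183, and the combination gave 333 gained and 248 lost and another split 304. Median bounds on the folds were at least 1.68-fold for those gained and at least 3.10-fold for those lost under the combination.

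Adding lithium to valproic acid changed 2.91% of the probes tested. Against valproic acid alone the combination had 97 probes up and 278 down, together 375. A block for the set gave 1545, 639 up and 906 down. Within the set of 8 arrays, with 1 array of the combination, 319 passed, and within the set of 4 arrays, with 1 of valproic acid, 32, each lone array assumed to vary like the other groups. Of the 319, 318 moved the same way in the set of 4, against 70.0% of all tested probes. The count was 189 without valproic acid replicate 2, and 199 and 212 without replicates 2 and 3 of the combination.

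Adding valproic acid to lithium changed 29.1% of the probes tested. Against lithium alone the combination had 2188 probes up and 1573 down, together 3761. The set of 4 arrays supplied 2 of the combination's arrays and none of lithium's, and with the set as a block 4442 probes passed, among them 3222 (85.7%) of the 3761. Within the set of 8 arrays, where the lone combination array was assumed to vary like the other groups, 3168 passed. The count was 2364 without lithium replicate 1, and 2356 and 2392 without replicates 2 and 3 of the combination. Valproic acid and lithium compared directly differed at 1869 probes (993 higher with valproic acid, 876 lower), at 3459 with the set as a block and at 3175 within the set of 8. That count was 1143 and 1229 without lithium replicates 1 and 2.

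Each agent's changes were set against its changes in the presence of the other, between comparisons that share no array. The changes with valproic acid in the presence of lithium had a slope of 1.02 on those in its absence (pooled jackknife SE 0.207). It ran from 0.83 to 1.08 as single arrays were left out, and was 0.862 with the set as a block. The changes with and without lithium correlated at 0.781 across probes without the block and at 0.826 with it. Without the block 2193 probes passed in both in the same direction against 8 in opposite directions, where independent lists would share 477.2. For lithium the slope was 0.428 with a jackknife SE, pooled over the arrays, of 0.442, on which it is not set apart from 0 or 1. With the set as a block the slope was 0.50. Lithium's changes with and without valproic acid correlated at 0.360 across probes without the block and at 0.519 with it. The unblocked slope ran from 0.211 without valproic acid replicate 1, and 0.235 without replicate 1 of the combination, to 0.638 without growth factors only replicate 1. In lithium's case 160 probes passed in both in the same direction and 2 in opposite directions, where independent lists would share 17.5. The slopes of the agents were not tested against each other, and the difference in lithium's effect was tested per probe by the interaction.

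**Figure D4:**
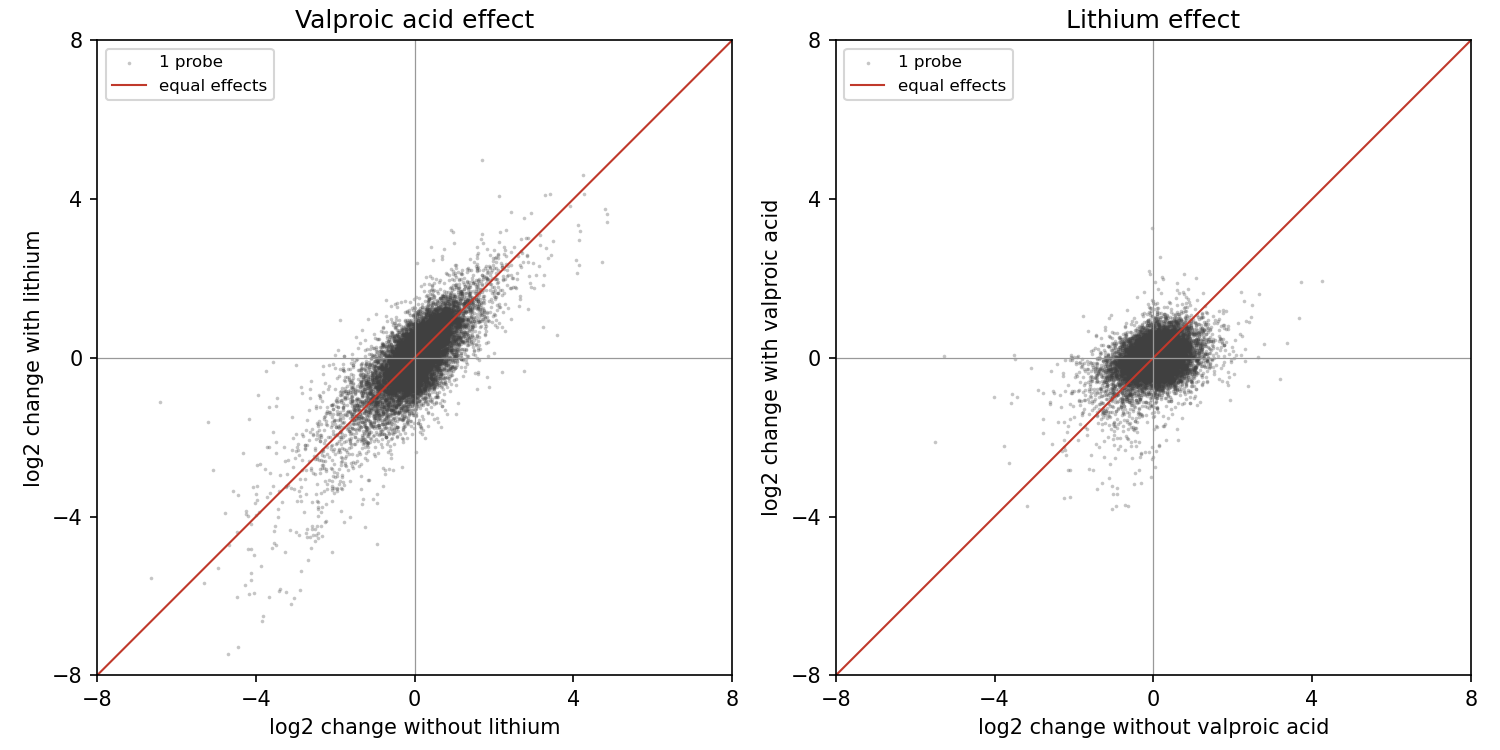
Log2 changes of all 12907 tested probes for valproic acid (left, without lithium on the x axis and with it on the y axis) and for lithium (right, without and with valproic acid), 1 point per probe, with a line of equal effects. The correlation across probes was 0.781 on the left and 0.360 on the right, without the set as a block. With the block, not drawn, it was 0.826 and 0.519.

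The interaction, a test of departure from additivity, passed at 116 probes (0.899%), 53 with a positive and 63 with a negative value. Whether chance can be excluded for this count stays open, as given below. The balance depended on the filter: among probes detected on all 12 arrays 11 were positive and 36 negative. A block for the set gave 437, the 116 among them, and the set of 8 arrays alone gave 105, with the lone combination array assumed to vary like the other groups. At 77 of the 116 the interaction had the opposite sign to the sum of the single changes, much as over all tested probes (65.6%), where shared arrays push both apart by chance. ILMN_2719256 rose less under both agents than the sum of its single changes (interaction -2.31, SE 0.35, limma adjusted p = 0.00664), and ILMN_2736774 had a fitted interaction of -2.77 (limma adjusted p = 0.0101). The combination's arrays did not detect ILMN_2736774, so the size of that value depends on the background level and is no estimate. Without background correction neither passed, and on the deposited log2 values ILMN_2736774 did not pass. The count ran from 57 to 201 as single arrays were left out: 57 and 74 without valproic acid replicates 2 and 3, 63 without lithium replicate 2 or 3, 76 without growth factors only replicate 3, and 201, 61 and 68 without replicates 1, 2 and 3 of the combination.

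Many probes were called in the same direction under both single agents. Of the probes changed by each, 307 rose and 441 fell under both agents, and 41 moved in opposite directions, where independent lists would share 138.1 in the same direction. Both comparisons use the same 3 control arrays. Unchanged groups simulated against such controls gave a correlation of 0.50 and a covariance of 0.0531, against an observed correlation of 0.549 and covariance of 0.253. Changes had the same sign under both agents at 67.8% of all tested probes, against 66.6% in the simulation. The simulated groups gave no shared call. Without any change hardly a probe can be called, so that count says nothing about the overlap. That simulation leaves out the sets of arrays. Part of the overlap may come from the shared controls, which are too few to split into parts of at least 2. The number of probes changed in the same direction was 2232 with the set as a block and 2095 within the set of 8 arrays, and 491, 386, 325 and 318 without growth factors only replicates 2 and 3 and lithium replicates 2 and 3. In the overall test 4813 probes differed among the 4 groups, and 7471 with the set as a block.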

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

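The test of whether the sets account for the interaction, and the blocked counts of other groupings, were chosen only after the result was seen. A difference between lithium's effect with and without valproic acid, tested by the interaction, singled out 116 probes, a count that fell to 76 without growth factors only replicate 3, 63 without lithium replicate 2 or 3, 57 and 74 without valproic acid replicates 2 and 3, and 61 and 68 without replicates 2 and 3 of the combination, and rose to 201 without its replicate 1. Among the named probes it singled out ILMN_2719256, with an interaction of -2.31, and ILMN_2736774, with a fitted value of -2.77 that depends on the background level, as the combination's arrays did not detect it. The unequal split of the sets over the groups was tested first. With the set as a block the median ratio of the blocked to the unblocked interaction over the 116 probes was 0.947 (5th to 95th percentile 0.814 to 1.11), and all 116 passed. This could hardly come out otherwise. Without the block a difference between the sets also widens the spread within groups, so probes with a large one were unlikely to be called. The test therefore cannot decide on the split as the source. Compression at the limits of the measured range stays open for part of the probes: 52.6% of them (61 of 116, exact binomial interval 43.1% to 61.9%) had a group detected on none of its arrays or a mean above the 99th percentile, against 17.4% of all tested probes. The other probes had no group at a limit so defined, although a group detected on only some of its arrays is not counted there. The share also takes no account of the sign of the interaction, so it does not measure compression itself. With a filter for detection on all 12 arrays 47 probes passed. An effect of both agents together on these transcripts, which the design names, remains open.

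For the interaction count of 116, 4 of 100 regroupings of the 12 arrays gave as many probes, the real one included, and the highest other count was 3185. A regrouping also moves the agents' own effects into the spread, whose median SD was 0.329 for the real groups and 0.454 for the others, and 94 of 99 other regroupings called none, so whether chance can be excluded for the interaction stays open. That count, many times the real one, points to a structure of the samples: the grouping kept the combination whole, mixed the other treatments and drew the arrays of the set of 4 into 2 of its groups. It also put valproic acid replicates 1 and 3 together with growth factors only replicate 1, so valproic acid's own effect could enter the contrast. With the set as a block, which takes up part of such a grouping, this regrouping called 0. These sources were not told apart. Another regrouping, with 285 probes, called 3430 with the block against 437 for the real groups. For the overall test 2 of 100 regroupings gave as many probes as the real 4813, and the highest other gave 5379. It kept the growth factors only group whole and put valproic acid replicate 1 with replicates 2 and 3 of the combination, a group wholly from the set of 4, and with the block it gave 1223 against 7471 for the real groups, though the block itself takes up much of a grouping that follows the sets.

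The deviation of the 4 arrays together from their group means was weighed as a second pattern. An additive difference in background would vanish in bright probes, but the set difference net of error had an SD of 0.60 on the log2 scale in the brightest of 4 equal bins of probes (0.584 to 0.609 as single arrays were left out), which argues against it. Quantile normalization as the source is argued against by median scaling, under which deviations of these arrays from different groups still correlated at a median of 0.706 (0.602 to 0.782). No label gives a biological difference between the sets, so no biological explanation was tested. Raw signal split by set as well. Median raw intensity was 96.3 to 114.1 in the set of 4 and 117.2 to 142 in the set of 8. Between 45.35% and 46.8% of probes were detected per array in the set of 4, and between 42.26% and 45.22% in the set of 8. What set these arrays apart stays open.

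With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Any other split mixes the compared groups, so their difference enters the spread and low counts follow from that as well. In 5 of the 6 pairwise comparisons the real split alone, 1 of 10, gave as many probes: 3248 for valproic acid, 1108 for lithium, 3761 for the combination against lithium and 1869 for valproic acid against lithium, where the highest other split gave 0, and 5099 for the combination against growth factors only, where it gave 936. For the combination against valproic acid, 2 of 10 splits did, as a split gave 3603 against the real 375. Both of these other splits follow the sets exactly, all 3 arrays of the set of 4 against the rest, and point to that structure of the samples. With the set as a block the real splits gave 7160 and 1545.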

How the results depend on the processing

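The set of arrays, as a block or by itself, the replicate numbers of the deposited log2 table, and for the overlap of the single agents all settings but median scaling, the deposited values and the replicate block, the detection limit of 0.01, and every setting for the slopes and SDs of changes, were chosen after seeing the data. Counts within 1.5 times of the 12-array value are not listed: 162 of 215. Others follow, against growth factors only unless stated. With the set as a block: 5939 (valproic acid), 3164 (lithium), 1545 (combination against valproic acid) and 3459 (valproic acid against lithium), the interaction at 437, the overall test at 7471 and the overlap at 2232. Within the set of 8, which held 1 array of the combination: 5051 for valproic acid, 3069 for lithium, 3175 for valproic acid against lithium and the overlap at 2095. Within the set of 4, with 1 residual degree of freedom and single arrays of 2 groups assumed to vary like the combination's: 1459 for valproic acid and 32 for the combination against valproic acid. The gain under the block came with a smaller median standard error (0.172 against 0.262 for valproic acid). With only the groups compared: 2094 for valproic acid and 135 for the combination against valproic acid, with fewer arrays to estimate the spread. A fold threshold of 2, which removes small changes by construction, gave 1886 (valproic acid), 672 (lithium), 3247 (combination), 2198 (combination against lithium) and 1163 (valproic acid against lithium). Detection on all 12 arrays (8539 probes tested): the interaction at 47.

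Under neither numbering did deviations of all same-numbered arrays correlate above 0.1. The sets entered this test, so pairing stays open. With the intensity table's numbers the lowest was -0.83, and 3 of 12 arrays correlated best with their own number. With the deposited log2 table's, correlations ran from 0.145 to 0.773 for number 1, -0.48 to 0.48 for number 2 and 0.0442 to 0.729 for number 3, and 7 of 12 arrays did. A replicate block gave 669 for lithium, 64 for the interaction and 467 for the overlap with the first numbering; the cause was not tested. With the second, on the deposited values, it gave 2104 for lithium, 965 for the combination against valproic acid, 2882 for valproic acid against lithium, 281 for the interaction and 1370 for the overlap. The deposited values without the block gave 1314, 424, 1924, 144 and 916, so most of the rise came with the block.

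Leaving out 1 array gave 2360 to 3488 probes for valproic acid, 448 to 1379 for lithium, 4109 to 5666 for the combination, 189 to 507 for the combination against valproic acid, 2356 to 4927 for it against lithium, 1143 to 2178 for valproic acid against lithium, 57 to 201 for the interaction, 3869 to 5475 for the overall test and 318 to 905 for the overlap. The interaction of ILMN_1212702, which did not pass, turned from -1.06 to 0.29 without background correction and to 0.15 on the deposited values, with or without the replicate block; the cause was not tested. Without background correction the interaction of ILMN_2719256 was -1.19 and that of ILMN_2736774 -0.94, and the latter was -1.23 on the deposited values; none passed. Of 500 other values, 470 stayed within their spread or on their side of the threshold, 12 moved, 4 fell short of the threshold, 11 newly passed and 3 reversed. The chip as a block, the gene lists and 1 probe per gene were not run. Signal over background limits probes near the detection limit, whose folds are bounds.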

Other observations

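The test with different control arrays for each agent was chosen only after the result was seen. Lithium and valproic acid may act on some of the same transcripts in these cultures: the covariance of their changes across probes exceeded that of simulated unchanged groups with shared controls by 0.20 (jackknife SE over arrays 0.0703). With different control arrays for each agent the mean covariance was 0.186 (jackknife SE 0.109) over 6 pairings, 0.255 (jackknife SE 0.0422) with the set effect removed, and 0.27 and 0.289 in the 2 pairings within the set of 8 arrays. As the first of these lay within 2 SE of 0, shared controls stay open as a source over the 12 arrays taken without regard to set. With the set effect removed the mean lay beyond 2 SE of 0, and both pairings within the set of 8 were above 0. Where the set is allowed for, these values argue against shared controls as the only source. A common shift in cell types or in cell maturation under both agents would give such an overlap too, and was not tested, as the probes have no gene names here.

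The balance of the changes varied with brightness. Among probes changed by lithium, 52.0% rose in the brightest of 4 equal bins of probes and 29.8% in the dimmest, and with the set as a block 60.4% and 38.2%. For the combination these shares were 57.9% in both bins without the block. No test of these differences was run. Groups were fully separated, with no overlap of their 3 arrays, at 44.5% of probes for the combination against growth factors only. The share was 48.4% for the combination against lithium, where the set of 4 supplied arrays of the combination alone. For the combination against valproic acid it was 17.7%. Chance gives 10% if the arrays are exchangeable, which the unequal split of the sets puts in doubt. An excess over 10% therefore does not measure the agents' effect alone.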
